A study of Xenopus laevis with 18 samples.

How the data were processed

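Transcript abundance was measured by RNA sequencing in whole embryos of the African clawed frog Xenopus laevis, J strain, at 18 stages of the Nieuwkoop and Faber (NF) series, with 1 library per stage. Per the labels' protocols, embryos were snap frozen, total RNA was extracted with TRIzol, ribosomal RNA was removed with a RiboZero kit, and libraries were made with a ScriptSeq kit. Removal of ribosomal RNA, unlike selection of poly(A) tails, keeps maternal transcripts with short tails in the library, so a change of tail length alone does not move a transcript in or out of these libraries. The library with the stage label 8.5 has a title that reads NF8_II, and the stage label was used. By the stage labels no stage has separate samples. Stages were therefore placed in 5 windows from the stage label alone, namely pre-midblastula (NF 0 to 7, n = 5), blastula (NF 8 to 9, n = 3), gastrula (NF 10 and 12, n = 2), neurula (NF 14 to 20, n = 4) and tailbud (NF 23 to 33, n = 4). Every SD, and the spread behind every test between windows, thus comes from neighbouring stages of a window. This spread holds real change during the window as well as technical spread. Tests of a trend over stage instead measure spread around a curve or line, or permute stage order.

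CASAVA 1.8.2, Trimmomatic, Bowtie and RSEM are named in the submitters' processing notes, with no role or order. The reference transcripts and the genome build are not given in the sources used here. The deposited table held 31085 rows, of which 30993 were Xenopus sequences and 92 were ERCC spike-ins, synthetic RNAs added to a sample as a yardstick. The amount of spike-in added is not given in the sources used here. In 9 of the 18 columns the deposited values were TPM, an abundance relative to a fixed total over all transcripts, since each column summed to 1000000 within rounding. The other 9 deposited columns were on the same scale but summed to between 1.48% and 2.72% over 1000000, for a reason not given in the sources used here, so they were not TPM as deposited. The design fixed beforehand had assumed TPM throughout. Both kinds of column were made comparable by leaving out the spike-in rows and rescaling the Xenopus rows of each library to 1000000, and these values are called TPM below. The kind of column was treated as a possible batch. The columns of NF 0 to NF 8 also carry a suffix in the file header whose meaning is not given in the sources used here. It covers every pre-midblastula library and 1 blastula library, so a difference in handling that goes with it cannot be separated from the earliest stages. No read counts were used here and TPM keeps no depth, so the depth of each library is unknown and no counting interval or detection floor is given. A value of 0 says only that a row was listed at 0, since 130 Xenopus rows and 3 spike-in rows had a 0 in a library whose neighbouring stages were both at 10 or more.

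None of the Xenopus row names matched the table of gene names used here (0 matches), so no gene is named. Gene lists fixed before the data were examined, and the parts of the rule for named genes that need a symbol, were not run for this reason. In their place rows were grouped by their time course. Lost rows had a mean of at least 10 TPM in the pre-midblastula window and under 1 TPM in the tailbud window. Gained rows had the opposite. Transient rows were under 1 TPM in both of these windows and at 10 TPM or more in a window between. Rows present throughout had a mean of at least 10 TPM in every window. These classes were defined after the data were seen. The few row names printed are the 2 largest rises and 2 largest falls from the pre-midblastula to the tailbud window under the fixed rule without its symbol condition, namely adjusted p under 0.05, a mean of at least 10 TPM in the higher window and no overlap between the libraries of both windows.

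Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), over the 21670 rows with a mean of at least 1 TPM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds on this scale understate the change of low rows. The 5 windows entered 1 fit over all 18 libraries, so every comparison shares 1 estimate of the spread. Windows were not equally spread. The robust SD of the log2 change was 0.15 from NF 6.5 to NF 7 and 0.94 from NF 10 to NF 12. Both values are for rows with a mean of at least 10 TPM. The shared estimate may thus be too wide for the earliest window and too narrow for the gastrula window. A stage trend was tested as a natural spline with 4 degrees of freedom over stage order, and a linear trend over the 5 pre-midblastula libraries alone was tested on 17596 rows. On data simulated from these libraries, 200 rows were changed, drawn from the more abundant rows only. A 2-fold change was recovered for 57.5% of them in blastula versus pre-midblastula, 34.5% in gastrula versus blastula and 38.5% in neurula versus gastrula. The rate was 58.5% in tailbud versus neurula and 68.5% in tailbud versus pre-midblastula. Of the rows called there in gastrula versus blastula, 9.21% had not been changed. The spread was simulated as independent between libraries and, for each row, as equal in all of them, unlike the real windows. Far fewer rows changed than were called in most real comparisons. The rates thus do not hold for low rows, for windows of unequal spread or for changes as wide as those below. Single values per library were compared by two-sided exact permutation tests, in a family of 21, and trends of a single value by permutation of stage order, exact where n was under 10. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

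Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, scaling by the median ratio to the geometric mean library, array weights, each library left out in turn, NF 8 moved to the earliest window, a spline with 3 degrees of freedom and NF number as the time axis. Scaling by the spike-in total, values as deposited, the kind of column as a covariate or as separate subsets, each pair of windows alone and the removal of rows with an isolated 0 were added after the data were seen.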

Results

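The series followed messenger RNA through early development of Xenopus laevis, from the egg to the tailbud embryo, in rRNA-depleted total RNA of whole embryos. Its title sets protein against mRNA dynamics. Only the RNA libraries were analysed here. The 18 libraries fall into a pre-midblastula window of 5 stages, a blastula window of 3, a gastrula window of 2, a neurula window of 4 and a tailbud window of 4. The depth of the libraries is unknown. Rows of the table carry sequence names without gene symbols, so the comparisons below are between classes of transcripts defined by their time course.

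Libraries of later stages listed more rows above 0, and fewer rows at 10 TPM or more. Rows above 0 numbered 20453 ± 265 in the pre-midblastula window (SD, n = 5) and 26628 ± 745 in the tailbud window (SD, n = 4), a difference at the smallest p that the 126 splits allow (exact permutation test, p = 0.00794, adjusted 0.0139). Rows at 10 TPM or more fell from 13203 ± 66.4 (SD, n = 5) to 10473 ± 169 in the neurula window (SD, n = 4) and were 11317 ± 433 in the tailbud window (SD, n = 4). The 100 most abundant rows held 14.3% ± 0.734 of the Xenopus total in the pre-midblastula window (SD, n = 5) and 29.9% ± 2.06 in the tailbud window (SD, n = 4). Spike-ins took 41.9% ± 3.40 of the deposited total in the pre-midblastula window (SD, n = 5) and 22.2% ± 3.32 in the tailbud window (SD, n = 4). More of each tailbud library was thus Xenopus. TPM is relative to the Xenopus total, and per spike-in the median row was higher, not lower, in tailbud libraries, by 0.66 on the log2 scale. The numbers of rows at 10 TPM or more and the share of the 100 most abundant rows also differed between pre-midblastula and tailbud windows at p = 0.00794 by the exact permutation test.

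The total of Xenopus transcripts relative to the spike-ins was level to the end of gastrulation and rose afterwards. The ratio was 1.40 ± 0.198 in the pre-midblastula window (SD, n = 5), 1.48 ± 0.103 in the blastula window (SD, n = 3), 1.85 ± 0.247 in the neurula window (SD, n = 4) and 3.59 ± 0.680 in the tailbud window (SD, n = 4). The 2 gastrula libraries lay at 1.38 and 1.39. Tailbud libraries exceeded pre-midblastula libraries 2.57-fold (exact permutation test, p = 0.00794, the smallest of 126 splits, adjusted 0.0139) and neurula libraries 1.94-fold (exact permutation test, p = 0.0286, the smallest of 70 splits, adjusted 0.0353). Over all 18 libraries the ratio followed stage order with r = 0.81 (permutation p = 1e-05, the smallest that 100000 permutations can give) and rho = 0.82 (permutation p = 4e-05). Without the first and the last stage r was 0.77. In the 9 libraries whose deposited column exceeded 1000000 r was 0.79 (exact permutation p = 0.00312), and in the other 9 it was 0.88 (exact permutation p = 0.00128). From NF 0 to NF 12 no trend was detected (r = 0.24, n = 10, permutation p = 0.495), and from NF 14 to NF 33 r was 0.94 (n = 8, exact permutation p = 0.000843). These 6 correlations belong to a family of 18, and the adjusted p for r was 3e-05 over all libraries, 0.00374 and 0.00193 in both kinds of column, 0.524 to NF 12 and 0.00138 from NF 14.

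**Figure D1:**
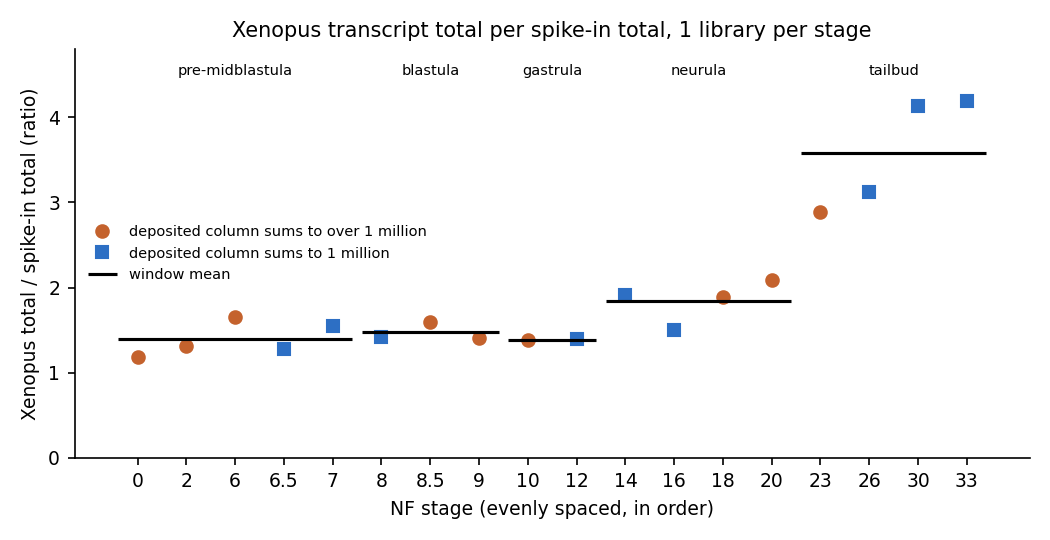
Ratio of the Xenopus total to the spike-in total (vertical axis) in each library against NF stage in order (horizontal axis); points are single libraries, their colour and shape give the kind of deposited column, and bars are window means. The ratio lies between 1.18 and 1.66 up to NF 12 and between 2.88 and 4.20 from NF 23.

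Neighbouring stages were nearly alike before the midblastula and differed most around gastrulation. Among 13674 rows with a mean of at least 10 TPM, between 0.819% and 0.958% changed 2-fold or more in each step up to NF 8. The share was 1.88% from NF 8 to NF 8.5, where 190 rows were higher and 67 lower, and 2.59% from NF 8.5 to NF 9, where 280 were higher and 74 lower. It was 13.7% from NF 9 to NF 10, 35.6% from NF 10 to NF 12 (1428 higher, 3445 lower) and 18.4% from NF 12 to NF 14. Later steps ranged from 2.49% to 6.27%. Spike-ins, which have no stage, changed that far in 1.54% to 9.23% of 65 rows per step, so by this share only the 3 steps from NF 9 to NF 14 lay above the range of the spike-ins. With spike-in scaling the step from NF 20 to NF 23, at 10.3%, lay above it too. With pseudocount 5 the steps from NF 9 to NF 10 and from NF 12 to NF 14 were at 9.38% and 9.43%. These lie close to the upper end of the spike-in range, which was not computed with that pseudocount. The robust SD of the log2 change was 0.94 for Xenopus rows from NF 10 to NF 12 and 0.29 to 0.41 in the 7 steps after NF 14, against at most 0.23 for spike-ins in any step. Correlation of log2 values with NF 0, across rows and therefore not over independent units, was 0.98 at NF 8, 0.92 at NF 9, 0.77 at NF 10, 0.44 at NF 12 and 0.28 at NF 14. Each step compares 1 library with 1 library, so it has no replicate check. The step from NF 8 to NF 8.5 is also where a suffix of unknown meaning in the column headers ends. The 5 steps that join both kinds of column were at 0.878%, 1.88%, 35.6%, 4.31% and 2.63%.

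**Figure D2:**
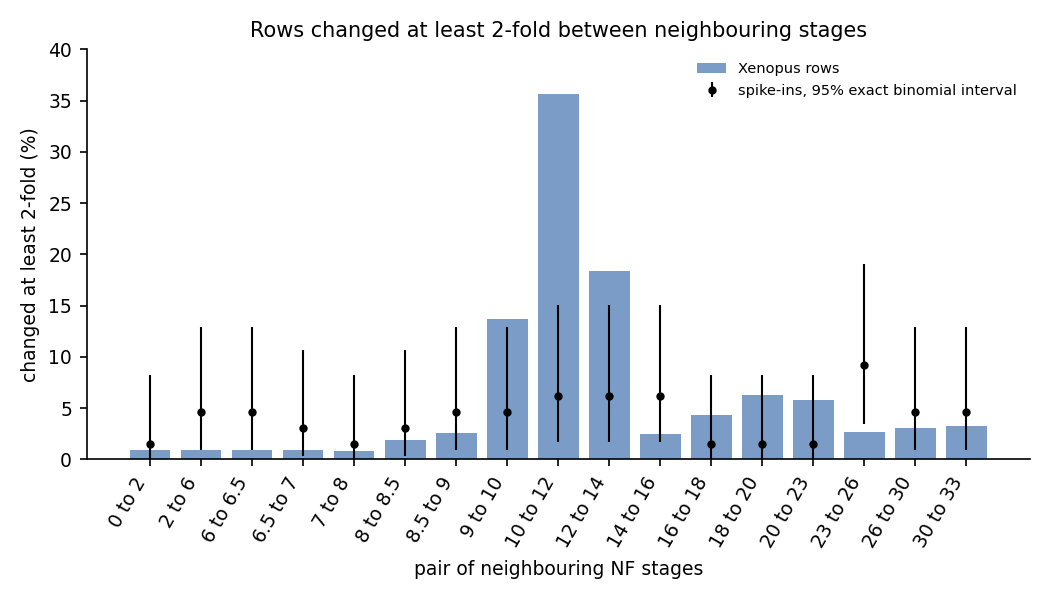
Percent of rows changed at least 2-fold (vertical axis) for each pair of neighbouring NF stages (horizontal axis); bars are the 13674 Xenopus rows and points are the 65 spike-ins with their 95% exact binomial interval. The bar from NF 10 to NF 12 stands at 35.6%, above the spike-in interval of 1.70% to 15.0%.

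Before the midblastula, when the embryo relies on maternal RNA, few rows passed the test for a trend with stage. Of 17596 rows, 13 rose and 74 fell from NF 0 to NF 7 (limma, adjusted p under 0.05), and 3050, or 17.3%, had an unadjusted p under 0.05, where chance gives 5%. The test has 3 residual degrees of freedom. On simulated data it recovered 54.5% of rows with a 2-fold change from NF 0 to NF 7, drawn from more abundant rows. The adjusted count thus does not bound the number of rows that changed. On the spike-in scale the majority turned, with 219 rising and 103 falling. The first 3 of these libraries have columns over 1000000 and the last 2 do not, so within these libraries the trend cannot be told apart from the kind of column. As a term beside the windows over all 18 libraries, the kind of column was called for 0 of 21670 rows with limma, and 1157 rows, or 5.34%, had an unadjusted p under 0.05, where chance gives 5%. In TPM at most 2 rising and 8 falling rows were called for the trend when any library was left out. Leaving out a library also lowers the power of so small a test, so this cannot tell a trend carried by single libraries from lost power. Without the filter on low values 0 rows were called in either direction.

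Few rows passed the test between blastula and pre-midblastula embryos. With limma, 1 of 21670 rows was higher and 0 were lower in the blastula window, while 974 rows had an unadjusted p under 0.05. The called row was listed at 0 in all 5 pre-midblastula libraries and also at NF 10, between values above 10 TPM at NF 9 and NF 12. The libraries of both windows did not overlap for 8.93% of rows, against 3.57% by chance. The count moved with the weight given to libraries and with NF 8. Array weights gave 1822 higher and 1730 lower, and leaving out NF 8 gave 141 higher and 45 lower. With both windows fitted alone, 1 row was higher and 1 lower, and 3358 of 17863 rows had an unadjusted p under 0.05. In that fit without NF 8, 237 rows were higher and 633 lower. The majority was thus the reverse of that without NF 8 in the fit over all windows. Without NF 8, no blastula library carries the header suffix of unknown meaning that all 5 pre-midblastula libraries carry. The counts without NF 8 thus cannot be told apart from a difference in handling that goes with the suffix.

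In the fit over all windows, gastrula embryos differed from blastula embryos in a large part of the rows tested. In TPM 2436 rows were higher and 6729 lower (limma, adjusted p under 0.05), of which 1972 and 4533 changed at least 2-fold, and the median log2 change was -0.30. The split depended on the scaling. Median ratio scaling gave 4217 higher and 3207 lower, with a median log2 change of 0.05. It brings the median ratio of rows above 0 in every library to the same level. A shift that these rows share is thus taken out, so the turn under this scaling is partly built in. Spike-in scaling gave 1881 higher and 5972 lower. In all 3 scalings 1912 rows were higher and 3230 lower. With only 2 gastrula libraries the count leans on each of them, and it was 1084 higher and 2518 lower without NF 12. Fitted alone, with 3 residual degrees of freedom, both windows gave 221 higher and 157 lower of 19007 rows, all at least 2-fold. Array weights gave 724 higher and 1716 lower. How many rows differed thus depends on the spread shared with the other windows. The fit alone turns the majority, but changes of at least 8-fold in the fit over all windows also lay mostly higher, with 526 against 156. It thus does not show a turn among smaller changes.

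Neurula embryos differed from gastrula embryos in 4305 rows that were higher and 7566 that were lower in TPM (limma, adjusted p under 0.05). Changes of at least 2-fold were seen in 3134 and 5041 of these. Median ratio scaling turned the majority, with 6871 higher and 4630 lower, but it takes out a shift that many rows share. Spike-in scaling does not, and it turned the majority too, with 5363 higher and 3919 lower. In all 3 scalings 4160 rows were higher and 3872 lower. Without NF 10 the counts were 2728 higher and 4060 lower, and with both windows fitted alone they were 2195 and 3628.

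Tailbud embryos had 6075 rows higher and 4994 lower than neurula embryos in TPM (limma, adjusted p under 0.05). The median log2 change was 0.07. With only rows of a mean of at least 5 TPM the majority and the median turned, with 3968 higher, 4653 lower and a median of -0.06. On the spike-in scale 13928 rows were higher and 884 lower, with a median of 0.88, and median ratio scaling gave 6837 higher and 5263 lower. In all 3 scalings 6018 rows were higher and 905 lower, and 591 rows were lower in TPM but higher per spike-in. Within the columns summing to 1000000 6994 rows were higher and 5311 lower. In the other kind, with 1 tailbud library, the counts were 484 and 367.

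**Figure D3:**
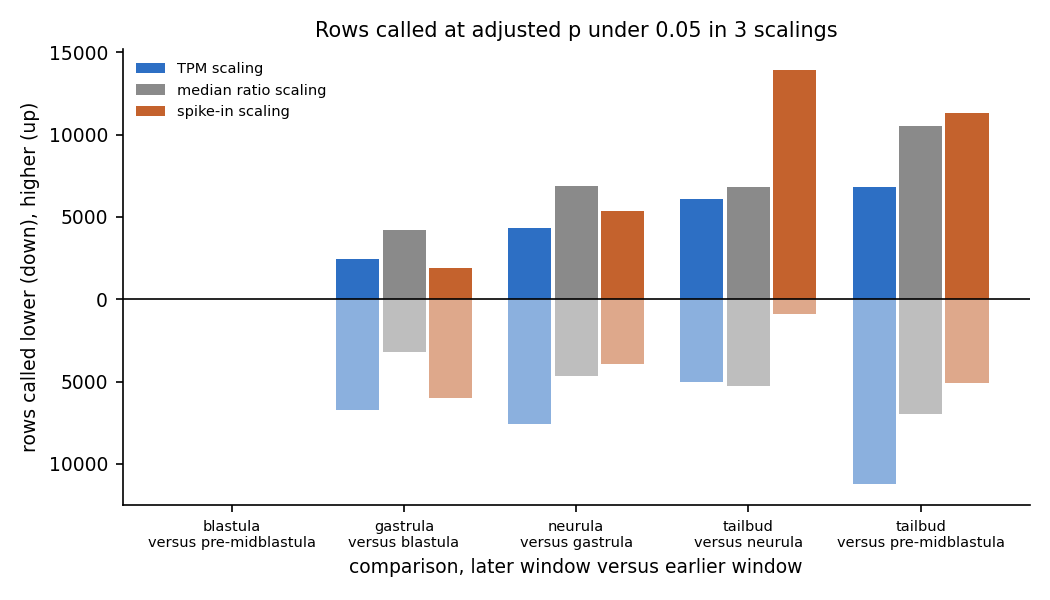
Rows called higher (bars upward) and lower (pale bars downward) at adjusted p under 0.05 for each comparison of windows (horizontal axis), in TPM, median ratio and spike-in scaling. In tailbud versus neurula the lower calls number 4994 in TPM and 884 on the spike-in scale.

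Over the whole course most of the transcriptome changed. The spline over stage was called for 20350 of 21670 rows, or 93.9% (limma, adjusted p under 0.05). Tailbud embryos had 6800 rows higher and 11231 lower than pre-midblastula embryos in TPM, of which 5610 and 8722 changed at least 2-fold, and the median log2 change was -0.57. Median ratio scaling gave 10555 higher and 6952 lower with a median of 0.38, and spike-in scaling gave 11290 higher and 5059 lower with a median of 0.66. In all 3 scalings 6798 rows were higher and 5162 lower, and 1641 rows were lower in TPM but higher per spike-in. The libraries of both windows did not overlap for 78.0% of rows, against 1.59% by chance.

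Rows of the lost class were mostly first below 50% of their pre-midblastula mean, and stayed there, at a stage from NF 10 to NF 14. The 444 lost rows held 3.80% of the Xenopus total in the pre-midblastula window and 0.0195% in the tailbud window, and 425 of them were called lower, a count largely fixed by how the class was chosen. Their share was 3.76% at NF 8 and 3.32% at NF 9, then 1.94% at NF 10, 0.531% at NF 12 and 0.166% at NF 14. For 91.2% of lost rows the first stage from which all values stayed below 50% of the pre-midblastula mean was NF 10, 12 or 14. On the spike-in scale this held for 86.7%. This measure dates a fall already made and not its start. In TPM the stage was NF 10 for 180 rows, NF 12 for 172 and NF 14, in the neurula window, for 53. The number of lost rows was 228 when the class was defined on the spike-in scale and 265 with median ratio scaling. The row XeXenL6RMv10016014m fell from 1799 ± 476 TPM (SD, n = 5) in the pre-midblastula window to 709 TPM at NF 10, 54.0 TPM at NF 12 and 25.2 TPM at NF 14, and was listed at 0 in every later library (limma adjusted p = 1.56e-09). The row XeXenL6RMv10048928m fell from 1376 ± 62.6 TPM (SD, n = 5) to 0.849 ± 0.533 TPM (SD, n = 4), a log2 change of -9.58 with a standard error of 0.435 (limma adjusted p = 1.33e-11). It stood at 543 TPM at NF 10 and 48.3 TPM at NF 12.

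Gained rows first reached 10 TPM over a longer span than the fall of lost rows, which was timed by a different measure. The 1761 gained rows held 0.0220% of the total in the pre-midblastula window and 15.1% in the tailbud window, and 1727 were called higher, which the choice of the class on these same windows largely fixed. Of these 1761 rows, 61 first reached 10 TPM by NF 9, 459 at NF 10 or 12, 693 between NF 14 and NF 20, and 548 between NF 23 and NF 33. Their share of the total was 0.136% at NF 8.5, 0.298% at NF 9, 1.63% at NF 10 and 4.87% at NF 12. The row XeXenL6RMv10011960m was listed at 0 in all 5 pre-midblastula libraries and stood at 92.5 TPM at NF 12, 1841 TPM at NF 20 and 5027 ± 2601 TPM in the tailbud window (SD, n = 4, limma adjusted p = 4.82e-11). The row XeXenL6RMv10033308m was listed at 0 up to NF 12 and again at NF 16, between 155 TPM at NF 14 and 278 TPM at NF 18, and reached 4719 ± 1854 TPM in the tailbud window (SD, n = 4, limma adjusted p = 9.99e-08).

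A small class was present only in between. The 92 transient rows were under 1 TPM in both outer windows, and most of them were highest at NF 10 (30 rows) or NF 12 (23 rows). They held 0.460% of the total at NF 10. The class had 54 rows when defined on the spike-in scale. In the fit over all windows 943 rows were called higher in the gastrula window than in both the pre-midblastula and the tailbud window. Only rows with a gastrula mean of at least 10 TPM were counted, and 532 of the 943 were higher by at least 2-fold. Both comparisons share the same gastrula libraries, so a chance high value there counts towards both. The count was made in TPM only. The 7545 rows present throughout held 74.7% of the total before the midblastula and 73.9% in the tailbud window. Of these 1375 were called higher and 4805 lower in TPM, with a median log2 change of -0.77, while on the spike-in scale their median was 0.54.

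**Figure D4:**
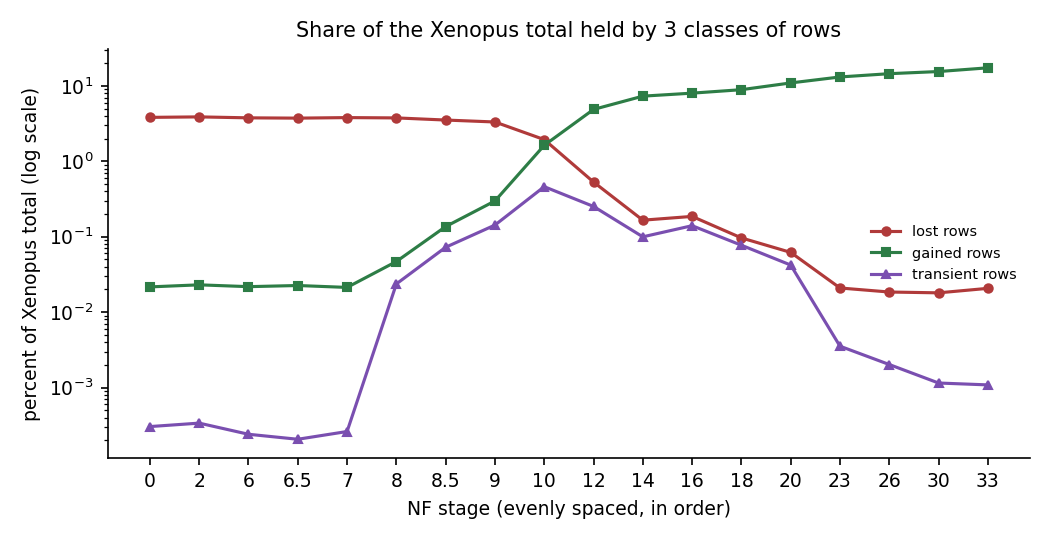
Percent of the Xenopus total on a log scale (vertical axis) held by lost, gained and transient rows in each library against NF stage in order (horizontal axis); each point is 1 library. Lost rows go from 3.82% at NF 0 to 0.0207% at NF 33 and gained rows from 0.0216% to 17.3%, which the definition of the classes fixes for the outer windows, and transient rows are at 0.460% at NF 10.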

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

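The tests of explanations in this part were chosen after the result was seen, except that the bound for the split test on unadjusted p was set before its value was computed. Library values in the 3 windows with 4 or 5 libraries were searched for a library far from the others. Of 42 window and measure pairs, 3 stood out, and chance gives about 2.1. NF 2 had more rows than the other pre-midblastula libraries, with 17611 rows at 1 TPM or more and 13318 rows at 10 TPM or more. Row XeXenL6RMv10016014m stood at 25.2 TPM at NF 14 and was listed at 0 in the other 3 neurula libraries, which follows its fall over the preceding stages.

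The Xenopus total per spike-in total rose towards the tailbud stages. Were a few rows to take the gain, the median row would not move, but on the spike-in scale the median log2 change from neurula to tailbud was 0.88. Were processing that differed with the kind of column the cause, the rise would be missing within a kind, but the lower of both within-kind correlations with stage was 0.79. The size of the rise differed between the kinds, with a ratio of tailbud to neurula of 1.45 in columns over 1000000, where 1 library is tailbud, and 2.24 in the others. Without ERCC-00074, the most abundant spike-in, this ratio was 1.94 over all libraries. The labels give 0 spike-in doses, so a rise of polyadenylated and other non-ribosomal RNA per unit of total RNA, a candidate biological explanation, cannot be told apart from less spike-in added per unit of RNA or from ribosomal RNA removal that changed with stage.

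In the fit over all windows more rows were lower than higher in TPM, first in gastrula versus blastula embryos and again over the whole course. The first majority turned with both windows fitted alone (221 higher, 157 lower) and with median ratio scaling (4217 and 3207). All calls of the windows fitted alone were at least 2-fold, so they do not show a turn among smaller changes. The second turned with median ratio scaling (10555 and 6952) and spike-in scaling (11290 and 5059). Median ratio scaling takes out a shift shared by rows above 0 in every library, so a turn under it is partly built in. A larger share of the total taken by abundant rows would push the others down in TPM only. For gastrula versus blastula the median log2 change on the spike-in scale was still -0.33. The median row thus fell per spike-in too, provided that spike-ins were dosed alike in these libraries. The Xenopus total per spike-in total was nearly level between these windows (means 1.48 and 1.39), so this scale adds little to TPM here. The 100 most abundant rows did go from 15.9% of the total in the blastula window to 26.3% in the gastrula window. How much of the fall this shift made was not tested. For tailbud versus pre-midblastula the median on the spike-in scale was 0.66, so there the fall of the median row in TPM is consistent with such a shift of composition under the same proviso. A loss of maternal transcripts during gastrulation stays open as an explanation of the first.

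Other groupings of the same libraries were compared with the real windows. For tailbud versus pre-midblastula 1 of 100 splits, the real one, gave as many calls (18031, highest other 16089). For tailbud versus neurula it was 1 of 35, the smallest share possible (11069, highest other 6733). For the stage trend it was 1 of 100 orders (20350, highest other 6163). Neighbouring stages resemble each other, so a split or order along the stages was bound to do well. The comparison thus shows that calls follow stage order, and it cannot exclude a difference in handling that runs along the stages. The highest other split of tailbud and pre-midblastula libraries set NF 2, 6, 6.5 and 7 against the rest. It is the real split with NF 0 moved, and it called most of the rows too. For the pre-midblastula trend 1 of 60 orders gave as many calls (87, highest other 0), although 1 other order came to 2781 rows at an unadjusted p under 0.05 beside 3050 in the real order, and the real order also runs along the kind of column. For blastula versus pre-midblastula 17 of 56 splits gave as many calls (1, highest other 3), but a count of 1 lies at the floor and separates little. With both windows fitted alone and rows counted at an unadjusted p under 0.05, 3 of 56 splits gave as many rows (3358, highest other 3913, with NF 7 in the place of NF 8), so chance cannot be excluded there either.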

How the results depend on the processing

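Spike-in scaling, values as deposited, the column subsets and covariate, windows fitted alone, removal of rows with an isolated 0, and all alternatives of the spike-in ratio, the row classes and the neighbouring stages were chosen after the data were seen. Over all alternatives 308 of 379 counts of calls lay within 1.5 times the reported count. Many of these alternatives leave out a library from outside the comparison or set counts near the floor side by side, so this tally shows little by itself. All 123 log2 changes of the 4 named rows kept direction and threshold, which their choice as the largest changes without overlap made likely. All 11 values of the spike-in ratio kept direction and threshold too. Of 85 values for neighbouring stages 30 moved by more than 1.5 times. Pseudocount 5 gave 9.43% from NF 12 to NF 14, and pseudocount 0.1 gave 2.18% from NF 0 to NF 2 and 2.13% from NF 7 to NF 8. No paired analysis was possible because each stage has 1 library, and the number of a library within its window gives only its order there and pairs it with no library of another window. Gene list tests and their alternatives, and the named genes that need a symbol, were not run, since no row name matched a gene name. Depth is unknown and limits the low rows to an unknown degree. Where no cause is named below, the cause was not tested.

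For blastula versus pre-midblastula, pseudocount 0.1 gave 20 higher and 2 lower, no filter 3 higher, array weights 1822 and 1730, NF 8 in the earliest window 155 and 48, only columns summing to 1000000 7 and 2, only columns over 1000000 45 and 23, rows with an isolated 0 removed 0 higher (the called row was among those removed), and both windows alone 1 lower. For gastrula versus blastula, median ratio scaling gave 4217 higher and 3207 lower, array weights 724 and 1716, only columns over 1000000 1036 and 2664, and both windows alone 221 and 157. For neurula versus gastrula, median ratio scaling gave 6871 and 4630, array weights 920 and 1997, spike-in scaling 3919 lower, only columns summing to 1000000 1175 and 1784, and both windows alone 2195 and 3628. For tailbud versus neurula, a filter at 5 TPM gave 3968 higher and 4653 lower with fewer rows tested, which turns the majority, spike-in scaling 13928 and 884, values as deposited 3267 lower, and only columns over 1000000, with 1 tailbud library, 484 and 367. For tailbud versus pre-midblastula, no filter gave 10649 higher with more rows tested, a filter at 5 TPM 3953 higher with fewer, median ratio scaling 10555 and 6952, and spike-in scaling 11290 and 5059. For the pre-midblastula trend, no filter gave 0 rising and 0 falling, a filter at 5 TPM 23 rising, array weights 26 and 114, NF 0 to 8 8 and 44, spike-in scaling 219 rising and 103 falling, values as deposited 4 and 20, and rows with an isolated 0 removed 22 rising. Columns of 1 kind hold fewer libraries, and a lone library of a window was assumed to vary like the others.

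With each library left out in turn, the ranges were 1 to 141 higher and 0 to 45 lower for blastula versus pre-midblastula (the highest without NF 8), 1084 to 3532 and 2518 to 8343 for gastrula versus blastula (the lowest without NF 12), 2728 to 4761 and 4060 to 8882 for neurula versus gastrula (the lowest without NF 10), 5203 to 7083 and 4112 to 5872 for tailbud versus neurula, and 6329 to 7001 and 11010 to 11405 for tailbud versus pre-midblastula. They were 19869 to 20443 for the stage trend, 0 to 2 rising and 0 to 8 falling for the pre-midblastula trend, and 2.42 to 2.73 for the spike-in ratio of tailbud over pre-midblastula. Row classes moved by more than 1.5 times in 3 of 80 alternatives, namely lost rows with median ratio scaling (265) and spike-in scaling (228) and transient rows with spike-in scaling (54).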

Other observations

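The bounds of the 3 tests on gained rows below were set before their values were computed, but after the share of gained rows in each library had been seen. The figures on returning and irregular rows come from searches made after the data were seen, and so does the count of rows against NF 6.5.

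The share of gained rows in the total was 0.0213% at NF 7 and 0.0469% at NF 8, which looked like a broad onset of new transcripts at NF 8. The tests did not bear this out. At NF 8 only 8.06% of the 1761 gained rows lay above all 5 pre-midblastula libraries, where chance gives 16.7% without ties, so the rise was not shared by most of the class. With the class chosen on NF 0, 2 and 6 alone, the share was 0.0239% at NF 6.5, 0.0770% at NF 7 and 0.0567% at NF 8, so NF 8 was 0.736 times the higher of both, but 2.37 times NF 6.5. Selection of rows that were low before NF 8 may thus account for the step from NF 7 to NF 8 in the class as first defined. Rows of this class, chosen without NF 6.5, 7 or 8, were compared with their value at NF 6.5. At NF 8, 343 were higher, 335 lower and 1084 equal, and at NF 7, 341 were higher, 350 lower and 1071 equal. At NF 8.5, 815 were higher, 230 lower and 717 equal. A rise shared by many rows was thus seen in the library labelled NF 8.5, whose title reads NF8_II, and not at NF 8. The larger sums at NF 7 and NF 8 came with no majority of rows. Between NF 8 and NF 8.5 the header suffix of unknown meaning ends and the kind of column changes. These counts thus cannot tell an onset of transcripts at NF 8.5 from a difference in handling at that step. For RNA from a later library, the 50 most abundant gained rows of NF 8.5 held a part of the NF 8 excess that was 0.663 times their part of NF 8.5, between the bounds set, so this stays open for NF 8.5, while for the libraries from NF 9 on the same ratio was at most 0.0277. At NF 8.5 the share of gained rows above all pre-midblastula libraries was 36.2%, and at NF 12 it was 70.0%.

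Rows that fell from the pre-midblastula to the neurula window and rose again to the tailbud window numbered 3126, against 3216 if both changes were independent. Both changes share the neurula libraries, so a chance low value there counts towards both. With the neurula libraries divided between the changes, the counts were 1978 and 2363, against 2113 and 2693 for independent lists. In TPM the hypothesis of a set of transcripts that dip and return beyond independence thus found no excess. On the spike-in scale 6458 rows fell and then rose, with no independent value computed. The opposite course, a rise and then a fall, was seen in 1712 rows in TPM against 1426 if independent, and with the neurula libraries divided in 1077 against 858 and in 1199 against 1166. On the spike-in scale it was seen in 467 rows. A dip and return of at least 4-fold each was seen in 103 rows, and in 304 rows on the spike-in scale.

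Of 78 rows with a mean of at least 1000 TPM, 7 jumped between neighbouring stages with a spread of at least 1 on the log2 scale, while the median spread over the 78 rows was 0.30. These 7 rows held between 0.185% of the total at NF 0 and 4.70% at NF 20, and 5 of them were listed at 0 in some library. Spike-in ERCC-00077 was listed at 0 in 4 libraries, with a mean of 101 on a scale where all spike-ins of a library sum to 1000000.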
